A study of Mus musculus with 21 samples.

How the data were processed

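The samples were 21 RNA libraries of mouse tissue, 11 of whole brown adipose tissue and 10 of white vastus lateralis. Per the labels' protocols, RNA was column-purified, depleted of ribosomal RNA, reverse-transcribed from random hexamers and made into sequencing libraries by transposase tagmentation. The authors deposited a table of raw read counts per gene model for each tissue, with 1 column per library, a gene symbol and the length of each model in bases, per the file headers. Per the submitters' processing notes, bcl2fastq 2.17.1.14, TopHat2 2.0.14, Picard 2.2.4, SAMtools 0.1.19, featureCounts 1.4.6 and edgeR were used with genome build mm9. Their order, settings, strand handling and treatment of duplicates are not given in the sources used here. Without a stated strand, reads of overlapping and antisense genes cannot be told apart, and reads of near-identical genes can be split or lost. This concerns the ribosomal protein genes, which have processed pseudogenes, and the muscle myosins.

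Each table held 28541 gene models, and the same models in both. Of these, 1443 models share a symbol with another model (593 symbols), and each model was tested on its own. No coordinates are printed because the genome build of the tables was not used here; gene neighbours and overlaps were taken from a RefSeq gene table of assembly GRCm38.p6 by symbol. A single model, DQ539915, took 2.03% to 12.5% of the counts of a library.

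Library totals were 20219479 to 41773148 counts in BAT and 30479508 to 40328627 in WV. Replicate libraries were compared by a chi-square test of their counts, and the smallest value per gene was 32.9, so no pair was within sampling noise and all were kept as separate samples. The tables hold sums of reads without molecular identifiers, so counts are not independent molecules.

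Groups were taken from the genotype and tissue in the labels. Before the data were examined, the designs, gene lists, rule for named genes and most alternatives were fixed. Genes were filtered by edgeR's expression filter on genotype, libraries scaled by TMM and tested with edgeR 4.0.16 (R 4.3.3), by the quasi-likelihood F test with Benjamini-Hochberg adjustment and a threshold of 0.05. BAT was fitted with the style of the title number (short number or long tag) as a covariate, and WV without covariates. The BAT fit tested 16051 genes and the WV fit 14529. The difference of the genotype effect between tissues was the interaction term of a fit over all 21 libraries and 16632 genes. Standard errors of log2 changes are the change divided by the root of the F statistic. CPM values are counts divided by TMM-scaled library sizes, and list scores are means of log2 CPM with a prior count of 2.

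Of 36 gene lists for pathways and cell types, 32 were tested in BAT and 33 in WV with camera (limma 3.58.1) on voom values with a preset correlation between genes of 0.01, adjusted over the lists of a tissue. A list of sex-linked genes served only as a check of libraries. The lists overlap: Myh4, for example, is in the contractile and the fast-twitch list. Each was also tested with an estimated correlation, with fry, and by permuting the list score over all 200 relabellings within title style in BAT or all 252 relabellings in WV, an exact two-sided test.

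Genes were named by this rule. Irf4, Mstn and Ucp1 were always named, where tested. Up to 10 genes per direction with the largest change were named among those passing with a mean of at least 1 CPM and all BATI4KO libraries beyond the floxed mean, leaving out unnamed models, and up to 3 passing members of each list. Where fewer than 5 passed in a direction, the 5 smallest p were named and said not to pass. For the difference between tissues, the 5 smallest p in each direction were named. No list member qualified under the rule for lists, so the examples given for lists, Elmod2 in BAT and the 9 genes shared between tissues were chosen after their values were seen.

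Alternatives were other scalings (RLE, upper quartile, library totals), other filters, DESeq2 1.42.0, limma voom with and without quality weights, other thresholds, other covariates, each title style alone, a muscle score as covariate, abundant genes left out, and each library left out. Added after seeing the data were a correction for gene length, the 7 WV libraries with low Rmrp and Rpph1, the level of these RNAs as a covariate, the muscle score as covariate for the lists, the permutation of list scores, the fits of circadian clock members, and the lists under other scalings, filters, voom settings and left-out genes. On simulated counts drawn from the real means and library sizes, with 200 genes changed, the BAT step over 15889 genes recovered 43.5% of genes changed 1.5-fold, 82.9% of those changed 2-fold and 97.1% of those changed 4-fold. The WV step over 14264 genes recovered 21.1%, 77.8% and 100%, and the interaction step over 16440 genes 14.5%, 58.9% and 91.2%. The simulated genes varied independently, without differences between libraries that many genes share. These percentages are therefore a check of the steps and not the power of the real comparisons. In the real BAT fit, 0 of 39 skeletal muscle genes with a median log2 difference of +2.53 passed over all genes.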

Results

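RNA sequencing counts were available for 21 libraries of whole tissue from mice. The tissues were brown adipose tissue (BAT), the fat that burns lipid for heat, and the white part of the vastus lateralis (WV), a fast-contracting thigh muscle. BATI4KO mice were compared with floxed littermates, which carry the loxP-flanked gene. BATI4KO is taken here, from knowledge of the study, as loss of the transcription factor Irf4 in brown adipocytes, and the question was what this loss changes in the fat itself and in a muscle outside it. BAT had 5 floxed and 6 BATI4KO libraries, and WV had 5 of each. Total counts ran from 20219479 to 41773148 in BAT and from 30479508 to 40328627 in WV. The titles of 3 floxed and 3 BATI4KO libraries of BAT carry short numbers (1, 2 or 3), and all other titles carry long tags, as in FX_5497 for a floxed and KO_5492 for a BATI4KO library. The same 4 long tags occur in both tissues. The labels do not say what the numbers mean or whether each library is a separate animal, so p-values measure the spread between these libraries.

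Irf4, the targeted gene, fell in BAT of BATI4KO mice. Its level was 39.7 ± 16.9 CPM in floxed BAT (SD, n = 5) and 7.23 ± 0.55 CPM in BATI4KO BAT (SD, n = 6), a log2 change of -2.45 (SE 0.24; edgeR quasi-likelihood test, adjusted p = 0.0026). All 6 BATI4KO libraries, at 6.57 to 8.10 CPM, lay below every floxed library, at 23.9 to 59.8 CPM. Within the libraries with short numbers the log2 change was -2.43 (edgeR adjusted p = 0.396) and within those with long tags -2.48 (edgeR adjusted p = 0.057). In WV, Irf4 was at 3.70 ± 0.95 CPM in floxed and 2.66 ± 0.29 CPM in BATI4KO libraries (SD, n = 5 each), a log2 difference of -0.48 that did not pass (SE 0.19; edgeR adjusted p = 0.489). The labels do not give the deleted exons or which cells kept the gene, so this check of the labels is partial.

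**Figure D1:**
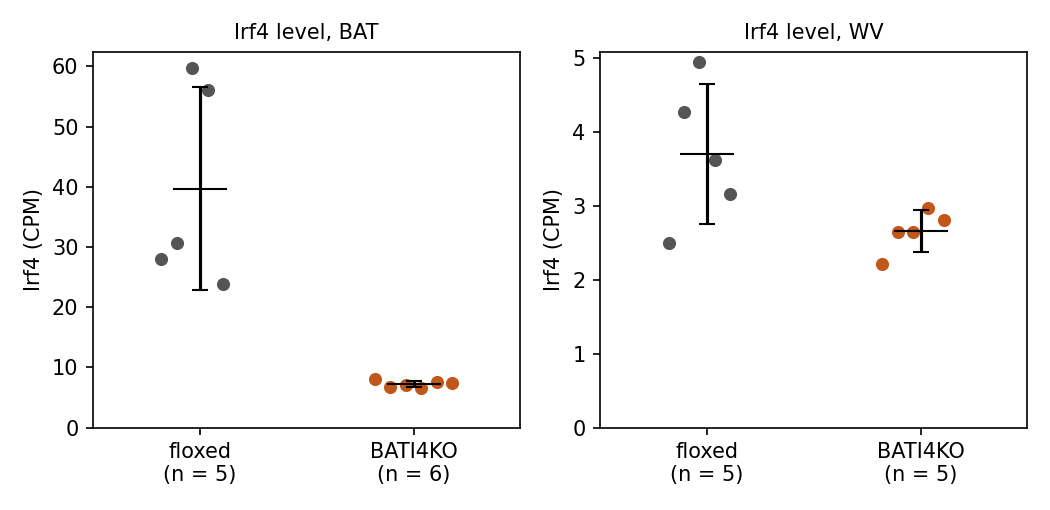
Irf4 level in CPM per library (points) in BAT and WV of floxed and BATI4KO mice, with the mean (long bar) and SD (whiskers). The BATI4KO BAT libraries lie at 6.57 to 8.10 CPM and the floxed ones at 23.9 to 59.8 CPM.

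The tissues carried the transcripts of their labels. Ucp1, the uncoupling protein of brown fat, was at 3797 ± 2178 CPM in floxed BAT (SD, n = 5) and at most 0.299 CPM in any WV library. Ttn, the giant spring protein of the sarcomere, took 8.72% to 18.8% of the counts in WV libraries. In BAT it took 0.00653% to 0.178% in 10 libraries and 1.62% in BATI4KO library 3. Rmrp and Rpph1, short noncoding RNAs of RNA-processing enzymes, differed by title style in BAT: Rmrp was at 299 to 1330 CPM in the libraries with short numbers and at 11.7 to 32.3 CPM in those with long tags. The Y-linked gene Ddx3y was at 132 to 245 CPM and Xist at 0.897 to 2.19 CPM over all 21 libraries.

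In BAT, 7 of 16051 tested genes changed between BATI4KO and floxed mice, 3 higher and 4 lower. Beside Irf4, the genes that fell were Adam12, a membrane-anchored metalloprotease, Fmo2, a flavin-containing monooxygenase, and Lrrc7, a scaffold protein of synapses. Adam12 went from 308 ± 129 to 106 ± 28.2 CPM (log2 -1.52, SE 0.20, edgeR adjusted p = 0.034) and Fmo2 from 38.6 ± 5.20 to 20.8 ± 3.74 CPM (log2 -0.89, SE 0.13, edgeR adjusted p = 0.0443). Lrrc7 was low throughout, at 0.528 ± 0.082 against 0.146 ± 0.043 CPM (log2 -1.84, SE 0.27, edgeR adjusted p = 0.0443). It falls under the level set for genes passing the test and is named as 1 of the 5 smallest p. The genes that rose were Gpr81, the lactate receptor that restrains lipolysis, Nthl1, a DNA repair glycosylase, and Limch1, an actin- and myosin-associated protein. Gpr81 went from 18 ± 5.87 to 59.1 ± 19.9 CPM (log2 +1.74, SE 0.26, edgeR adjusted p = 0.0443), Nthl1 from 1.38 ± 0.27 to 2.74 ± 0.19 CPM (log2 +1.02, SE 0.15, edgeR adjusted p = 0.0443) and Limch1 from 17.7 ± 3.72 to 32.2 ± 2.72 CPM (log2 +0.91, SE 0.12, edgeR adjusted p = 0.0279). These are SDs over 5 floxed and 6 BATI4KO libraries, and for all 7 genes the libraries of the genotypes did not overlap. Such separation was seen in 161 genes, 1% of those tested, where chance gives 0.433%.

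Several genes of interest in BAT did not pass. Ucp1 was at 3797 ± 2178 CPM in floxed and 2543 ± 1121 CPM in BATI4KO libraries (log2 -0.66, SE 0.21, edgeR adjusted p = 0.203). Mstn, which encodes myostatin, the secreted inhibitor of muscle growth, was near the floor of detection, at 0.143 ± 0.131 CPM against 1.1 ± 1.5 CPM. Its log2 difference was +2.84 (SE 0.84; edgeR adjusted p = 0.193), and it rested on 0 to 10 counts in floxed and 7 to 93 counts in BATI4KO libraries. The contractile muscle list, with a median of +2.53, had a mean log2 CPM above the floxed mean in 5 of the 6 BATI4KO libraries, and in BATI4KO library 2 its 2.94 lay within the 1.64 to 3.91 of floxed libraries. Cldn1, a tight-junction protein, had a log2 difference of -1.52 (edgeR adjusted p = 0.0524, and 0.0346 without floxed library 3 or 0.0439 without BATI4KO library 2), Parp10, an ADP-ribosyltransferase, +0.51 and Gramd1a, a sterol carrier of the endoplasmic reticulum, +0.49 (edgeR adjusted p = 0.139 for both). Cldn1 passed with RLE size factors (edgeR adjusted p = 0.049), without a filter (0.0146), with muscle, mitochondrial and globin genes left out (0.0458) and with the length correction (0.0467). It also passed by limma voom (limma adjusted p = 0.0462, and 0.0201 with quality weights) and by DESeq2 (DESeq2 adjusted p = 8.28e-07), as did Parp10 (0.00114) and Gramd1a (0.00181) by DESeq2.

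The number of BAT genes passing depended on the libraries and the test. Unadjusted p-values under 0.05 were found for 2366 genes, against 803 expected by chance, and DESeq2 called 388 genes, 207 higher and 181 lower. Within the libraries with short numbers 0 genes passed edgeR's test, with 1212 at an unadjusted p under 0.05. Within those with long tags 6 passed, of which 0 were among the 7. The count was 1 without floxed library 1 or FX_5497 or BATI4KO library 1 or KO_5492, 2 without floxed library 2 or FX_5503, 3 without library KO_5494, 4 without BATI4KO library 3 and 16 without floxed library 3. Irf4 passed each time. It was the 1 gene left without the covariate for title style and with a muscle score, the mean log2 CPM of contractile muscle genes, as a covariate, and the other 6 then had edgeR adjusted p-values of 0.072 to 0.0926 and of 0.139 to 0.426. Their log2 differences without the covariate were +0.86 for Limch1, -1.55 for Adam12, -0.89 for Fmo2, -1.84 for Lrrc7, +1.72 for Gpr81 and +0.995 for Nthl1. With the muscle score they were +0.88, -1.64, -1.03, -1.55, +1.98 and +0.99 in the same order, against +0.91, -1.52, -0.89, -1.84, +1.74 and +1.02 in the main fit. The count was 3 with upper-quartile scaling, where Fmo2 (-0.86), Lrrc7 (-1.80), Gpr81 (+1.77) and Nthl1 (+1.06) did not pass (edgeR adjusted p = 0.0561 to 0.0647). It was also 3 with a filter of 1 CPM, where Fmo2 (-0.88), Gpr81 (+1.75) and Nthl1 (+1.03) did not pass (0.0521 to 0.0558) and Lrrc7 was not tested. Fmo2 (-0.76) and Lrrc7 (-1.71) missed the threshold with library totals only (edgeR adjusted p = 0.0505 for both), and Lrrc7 (-1.84) without a filter (0.0704).

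Genes of skeletal muscle were higher as a group in BATI4KO brown fat. The list of contractile and calcium-handling genes had 39 measured members with a median log2 difference of +2.53, all 39 of them positive. None passed edgeR's test over all genes, and 38 were higher adjusted over the list alone. Examples are Actn3, the fast-fibre actinin (log2 +2.93), Casq1, the calcium buffer of the sarcoplasmic reticulum (log2 +2.61), and Myh4, the fast IIb myosin, at 92.0 ± 68.3 CPM in floxed and 601 ± 610 CPM in BATI4KO libraries. The camera test with a preset correlation gave an adjusted p of 5.1e-20, and adjusted p = 0.435 with an estimated correlation. Without BATI4KO library 3 the list's median was +1.27, and it was +2.79 within the libraries with short numbers and +2.01 within those with long tags. The fast-twitch and glycolytic list (23 members, 14 higher and 2 lower adjusted over the list alone) had a median of +2.16 (camera adjusted p = 2.36e-05; adjusted p = 0.435 with an estimated correlation). Its median was +1.08 without BATI4KO library 3, and +2.40 with short numbers and +1.66 with long tags. All contractile and calcium-handling genes of this fast-twitch list are also in the contractile list, so the 2 lists largely repeat each other. With the genes of the contractile list, mitochondrially encoded subunits and haemoglobins left out, only genes of glycolysis such as Ldha, Gapdh and Pgk1 stayed in the fast-twitch list. Their median was -0.10 (camera adjusted p = 0.561). The slow-twitch list (11 members, 3 higher and 1 lower adjusted over the list alone) had a median of +2.05 (camera adjusted p = 0.0485; adjusted p = 0.596 with an estimated correlation). Its call was lost without any of 6 single libraries: floxed 1 (median +2.28), floxed 3 (+2.56), FX_5497 (+1.73), FX_5503 (+1.95), BATI4KO 3 (+1.66) or KO_5414 (+0.62). It was also lost with a filter of 1 CPM (median +0.78, camera adjusted p = 0.2), with quality weights (+0.98, 0.124), with upper-quartile scaling (+2.10, 0.095), with library totals only (+2.19, 0.315) and with the same genes left out (+2.05, 0.194). Within each title style the slow-twitch list did not pass (+0.99 with short numbers, camera adjusted p = 0.257, and +2.95 with long tags, 0.0728), and its median by limma voom was +1.18. With the muscle score, which is the mean of the contractile list, as a covariate, the medians of the 3 lists became -0.002, +0.15 for slow-twitch and +0.07 for fast-twitch genes, and none passed (camera adjusted p = 0.498, 0.688 and 0.403).

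**Figure D2:**
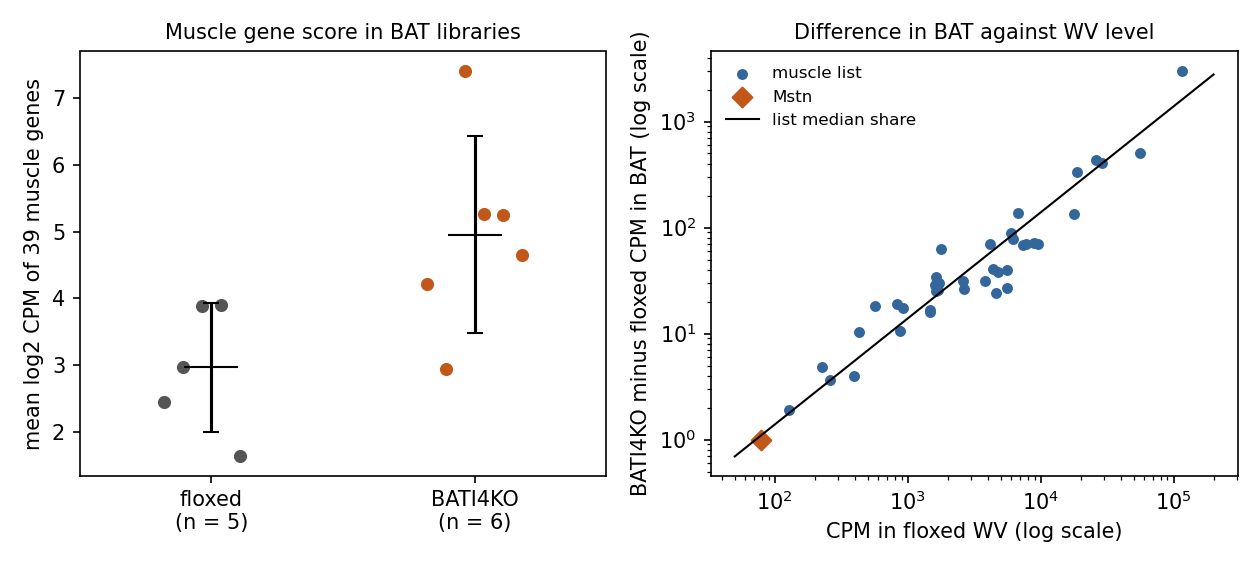
Left, mean log2 CPM of the 39 measured skeletal muscle genes per BAT library (points), with mean (long bar) and SD (whiskers); BATI4KO library 3 is highest at 7.40. Right, difference of mean CPM between BATI4KO and floxed BAT against mean CPM in floxed WV, both on log scales, for the muscle list and Mstn; the line is the list's median share of the WV level, 1.39%.

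Genes of mitochondrial energy metabolism were slightly lower as groups in BATI4KO BAT. Among the 78 measured nuclear-encoded subunits of oxidative phosphorylation 76 had a negative log2 difference, with a median of -0.23 (camera adjusted p = 2.82e-11; adjusted p = 0.496 with an estimated correlation). Their median was -0.36 within the libraries with short numbers and -0.04 within those with long tags, where the list did not pass (camera adjusted p = 0.485), and -0.12 without floxed library 3. Fatty acid oxidation genes had a median of -0.21 (24 of 25 negative; camera adjusted p = 1.24e-07; adjusted p = 0.435 with an estimated correlation). The list holds Acsl1, the acyl-CoA synthetase that activates fatty acids (log2 -0.43), and Pdk4, the kinase that shuts off pyruvate dehydrogenase (log2 -0.54). Tricarboxylic acid cycle genes had a median of -0.22 (20 of 20 negative; camera adjusted p = 1.26e-06; adjusted p = 0.435 with an estimated correlation). The 3 measured mitochondrially encoded subunits had a median of -0.25 (camera adjusted p = 0.0166; adjusted p = 0.435 with an estimated correlation), and without floxed library 3 this call was lost (median -0.21, camera adjusted p = 0.0683). The thermogenic programme of brown adipocytes had a median of -0.19 over 29 members (camera adjusted p = 0.00468; adjusted p = 0.435 with an estimated correlation). Its members went both ways: Gyk, a glycerol kinase, had a log2 difference of -0.98 and Ebf2, a brown adipocyte transcription factor, +0.53. No member of these lists passed over all genes. Adjusted over the list alone, 3 members were lower for fatty acid oxidation, 1 was higher and 1 lower for the thermogenic programme, and 0 passed in the other lists, by edgeR's test. In the libraries with short numbers the medians were -0.29 for fatty acid oxidation, -0.30 for the tricarboxylic acid cycle, -0.28 for mitochondrially encoded subunits and -0.19 for the thermogenic programme, and each of the 4 passed camera. With long tags they were -0.09 and -0.15 for fatty acid oxidation and the thermogenic programme, which passed, and -0.12 and -0.21 for the tricarboxylic acid cycle and the mitochondrially encoded subunits, which did not (camera adjusted p = 0.0728 and 0.26). Over all lists 6 were higher and 3 lower with long tags, 7 of them among the 14 of all libraries, against 5 higher and 9 lower. The call for mitochondrially encoded subunits was also lost with quality weights (camera adjusted p = 0.0612), without the covariate for title style (0.0653) and with the muscle score as a covariate (0.08). With that score the thermogenic programme did not pass either (camera adjusted p = 0.08), and the tricarboxylic acid cycle had a median of -0.11.

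Lists of protein synthesis and breakdown were also slightly lower in BATI4KO BAT. Cytosolic ribosomal protein genes had a median of -0.19 (79 of 79 negative; camera adjusted p = 2.41e-06; adjusted p = 0.651 with an estimated correlation), which became -0.03 without floxed library 3 (camera adjusted p = 0.351), the library with the highest Rmrp in BAT. It was -0.29 within the libraries with short numbers and -0.04 within those with long tags, where it did not pass (camera adjusted p = 0.425). Mitochondrial ribosomal protein genes had a median of -0.14 (67 of 73 negative; camera adjusted p = 1.98e-05; adjusted p = 0.596 with an estimated correlation). Their median was -0.20 with short numbers and -0.01 with long tags (camera adjusted p = 0.759), -0.22 without library FX_5497 and -0.08 without FX_5503. Proteasome subunits also had a median of -0.14 (30 of 31 negative; camera adjusted p = 0.000402; adjusted p = 0.596 with an estimated correlation), and -0.06 without library FX_5503 (camera adjusted p = 0.0715). The proteasome median was -0.15 with short numbers and -0.13 with long tags, -0.09 without floxed library 3 or BATI4KO library 3, -0.08 without BATI4KO library 1 and -0.21 without BATI4KO library 2. General adipocyte genes had a median of -0.07 (camera adjusted p = 0.0406; adjusted p = 0.435 with an estimated correlation), with Cd36, a fatty acid transporter, at -0.44. This call was lost without floxed library 3 (median -0.04) or FX_5503 (-0.10), or BATI4KO library 3 (-0.08) or KO_5494 (-0.09), and without floxed library 1 the median was -0.16. It was also lost with short numbers alone (-0.11, camera adjusted p = 0.102), with long tags alone (-0.08, 0.0728), with a filter of 1 CPM (-0.06, 0.0676), with quality weights (-0.09, 0.0795) and with the genes of muscle, mitochondrial and globin lists left out (-0.07, 0.0513). The median of this list was -0.04 by limma voom and with upper-quartile scaling. Without the covariate for title style the calls for general adipocyte genes (-0.04, camera adjusted p = 0.325) and the proteasome (-0.07, 0.0904) were lost, and mitochondrial ribosomal proteins had a median of -0.08. With the muscle score as a covariate general adipocyte genes (0.004, camera adjusted p = 0.403), the proteasome (-0.03, 0.575) and mitochondrial ribosomal proteins (-0.06, 0.308) did not pass. Adjusted over the list alone, 3 general adipocyte genes were lower, and 0 members passed in the other 3 lists by edgeR's test. With scaling by library totals only, the median of all genes became +0.13, that of general adipocyte genes +0.07 and that of mitochondrial ribosomal proteins 0.003, while the other 7 lists lower in BAT had medians of -0.12 to -0.004.

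Lists of immune genes were higher in BATI4KO BAT. Lymphocyte markers had a median log2 difference of +0.86 (15 of 15 positive; camera adjusted p = 1.72e-05; adjusted p = 0.435 with an estimated correlation), with 4 higher adjusted over the list alone. Library KO_5414 had a mean log2 CPM of 1.71 over this list, against 0.0211 to 0.546 in the other 5. The median was +0.45 without KO_5414 and +0.54 without FX_5503, +0.37 within the libraries with short numbers and +1.74 within those with long tags. The interferon response list had a median of +0.34 (25 of 26 positive; camera adjusted p = 1.35e-05; adjusted p = 0.496 with an estimated correlation), with 2 higher adjusted over the list alone. It includes Tap1, a peptide transporter of antigen presentation (log2 +0.77), and Cxcl10, a chemokine (log2 +0.88). The interferon median was +0.20 without library KO_5494, +0.18 with short numbers and +0.54 with long tags. No member of either list passed over all genes. Macrophage markers had a median of -0.05 and did not pass (camera adjusted p = 0.702).

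The other 17 BAT lists did not pass the camera test. Adjusted p was 0.0561 for endothelial markers (median -0.09), for smooth muscle and pericyte markers (-0.16) and for translation factors and the mTOR pathway, whose median of -0.13 differed in sign from the mean of +0.04. It was 0.0965 for lipolysis (-0.10), 0.107 for circadian clock genes (-0.17), 0.11 for immediate early genes (+0.23), 0.18 for the myostatin and activin pathway (+0.03), 0.254 for erythroid markers (+0.14) and 0.377 for myogenic regulators (+0.13). It was 0.429 for collagens and matrix (-0.02), 0.572 for nerve and Schwann cell markers (-0.07), 0.663 for fibroblast and preadipocyte markers (-0.06) and 0.702 for de novo lipogenesis (+0.09). Granulocyte and mast cell markers also had 0.702, with a median of -0.25 against a positive test direction. The adjusted p was 0.794 for secreted factors of adipose tissue (median -0.07, mean +0.16), 0.865 for white adipocyte genes (+0.07, against a negative test direction) and 0.986 for the stress response (+0.01, against a negative test direction).

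In WV, 1 of 14529 tested genes changed. Elmod2, a regulator of small GTPases, rose from 17.9 ± 2.92 CPM in floxed to 39.7 ± 6.78 CPM in BATI4KO libraries (SD, n = 5 each; log2 +1.15, SE 0.14, edgeR adjusted p = 0.0449), and was higher in 5 of 5 BATI4KO libraries than in any floxed library. In BAT the same gene was at 55.8 ± 16.2 CPM in floxed and 115 ± 34.8 CPM in BATI4KO libraries, a log2 difference of +1.02 that did not pass (SE 0.21; edgeR adjusted p = 0.14). Next in order in WV, none of them passing, were Dusp10, a phosphatase of stress-activated kinases, at 23.0 ± 6.18 against 64.4 ± 16.8 CPM (log2 +1.49, edgeR adjusted p = 0.0802), and Adh1, an alcohol dehydrogenase, at 22.6 ± 5.65 against 8.66 ± 2.37 CPM (log2 -1.39, edgeR adjusted p = 0.0802). Lonrf3 (log2 -1.28), Myrip (-1.40) and Inmt, a methyltransferase (-2.04), had an edgeR adjusted p of 0.0824, and Hdac9, a histone deacetylase (+0.80), and Ccbe1, a factor of lymphatic growth (-1.53), one of 0.106. Nr1d1, a repressor in the circadian clock that overlaps Thra in the GRCm38.p6 annotation, had a log2 difference of +1.18 (edgeR adjusted p = 0.128), and Cecr2, a chromatin remodelling factor, one of +0.79 (edgeR adjusted p = 0.175). Mstn was at 78.6 ± 30.7 CPM in floxed and 75.6 ± 30.8 CPM in BATI4KO muscle (log2 -0.06, SE 0.33, edgeR adjusted p = 0.974).

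**Figure D3:**
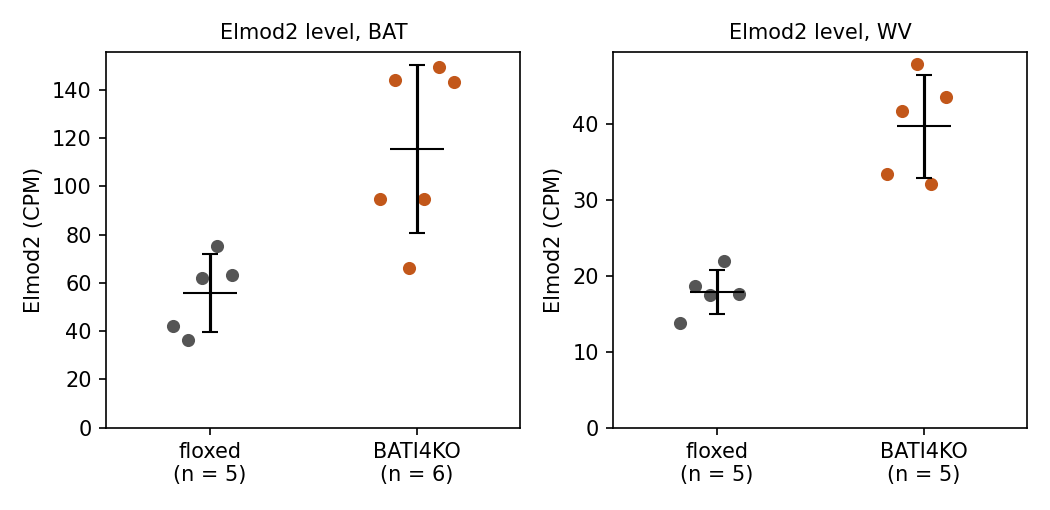
Elmod2 level in CPM per library (points) in BAT and WV of floxed and BATI4KO mice, with the mean (long bar) and SD (whiskers). The WV means are 17.9 and 39.7 CPM and the BAT means 55.8 and 115 CPM, of which the WV difference passed the test.

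Unadjusted p-values under 0.05 were found for 1295 WV genes, against 726 expected by chance, and DESeq2 called 97, 26 higher and 71 lower. Libraries of the genotypes did not overlap for 180 genes, 1.24%, where chance gives 0.794%. The edgeR count was 10 without library FX_5413 and 11 without library KO_5495. It was 0 without library FX_5415, FX_5497 or FX_5514 (1184, 861 and 1350 genes at an unadjusted p under 0.05) and without library KO_5492, KO_5493 or KO_5494 (1809, 794 and 1235). Elmod2 then had an edgeR adjusted p of 0.0902, 0.213 and 0.0968, and of 0.0546, 0.164 and 0.155, in the same order, and its log2 difference without any single library was +1.07 to +1.24. Without library KO_5496 the count was 1, which was Lonrf3 (edgeR adjusted p = 0.00904) and not Elmod2 (edgeR adjusted p = 0.079). Without FX_5413, Dusp10 and Adh1 (edgeR adjusted p = 0.0426 for both), Inmt (0.0276), Nr1d1 (0.0221) and Cecr2 (0.0139) also passed. Without KO_5495, Dusp10 and Adh1 (edgeR adjusted p = 0.0191 for both) and Ccbe1 (0.04) passed. Without a filter Dusp10, Adh1 and Inmt (edgeR adjusted p = 0.0243 for each) and Lonrf3 (0.0374) passed. By limma voom with quality weights Dusp10, Adh1, Lonrf3, Myrip, Hdac9, Nr1d1 and Cecr2 passed (limma adjusted p = 0.0188 to 0.0466), and by DESeq2 these, Inmt and Ccbe1 did (DESeq2 adjusted p = 6.32e-07 to 0.00195). With scaling by library totals only, which moved the median of all WV genes to -0.12, 0 genes passed edgeR's test, with 925 at an unadjusted p under 0.05, and Elmod2 (+1.02) had an edgeR adjusted p of 0.176. Elmod2 also did not pass with upper-quartile scaling (+1.13, edgeR adjusted p = 0.0585), a filter of 1 CPM (+1.142, 0.0633), the length correction (+1.11, 0.0729), the level of Rmrp and Rpph1 as a covariate (+1.33, 0.23) or the 7 libraries with low Rmrp and Rpph1 (+1.28, 0.519).

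Cytosolic ribosomal protein genes were lower as a group in BATI4KO muscle. The median log2 difference of the 79 measured genes was -0.47, all 79 were negative, 0 passed over all genes by edgeR's test and 63 were lower adjusted over the list alone. Rps25 was at 61.4 ± 16.1 CPM in floxed and 36.9 ± 4.46 CPM in BATI4KO libraries, and Rpl35 at 40.9 ± 15.4 against 19.9 ± 4.88 CPM. The camera test gave an adjusted p of 2e-43, and adjusted p = 0.629 with an estimated correlation. The list's mean log2 CPM was highest in libraries FX_5497, FX_5503 and FX_5514, at 5.87 to 6.02, and lay between 4.97 and 5.49 in the other 7 libraries of both genotypes. The same 3 libraries had 107 to 134 CPM of Rmrp, against 11.8 to 22.4 CPM in the others. Without them the 7 remaining libraries gave a list median of -0.19, and it was -0.11 with the level of Rmrp and Rpph1 as a covariate and -0.28 with the length correction.

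**Figure D4:**
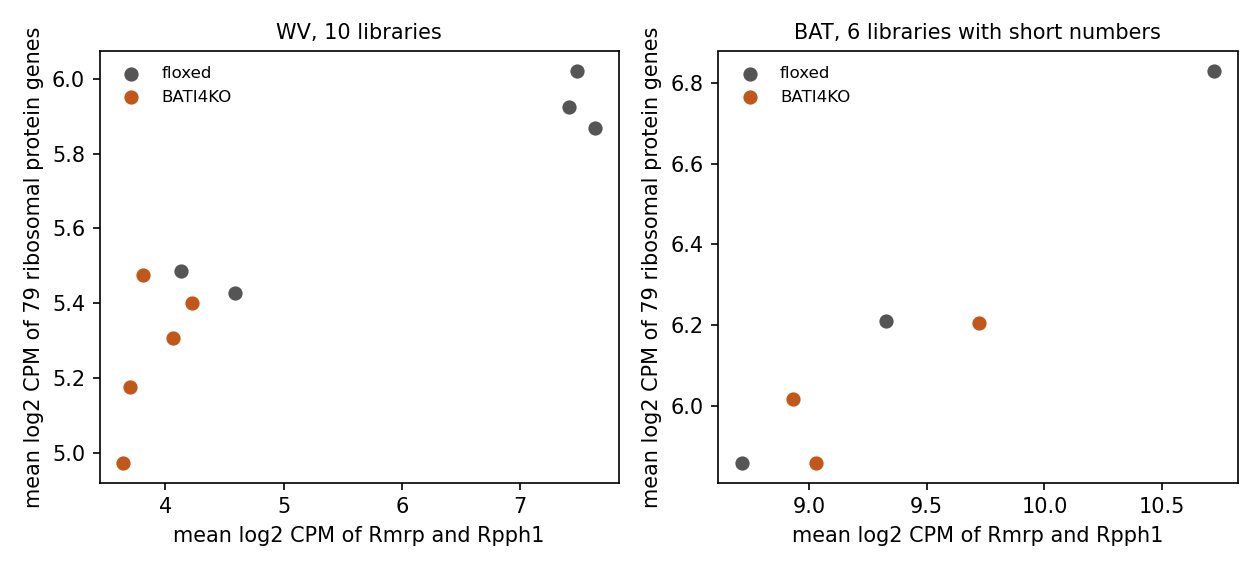
Mean log2 CPM of 79 cytosolic ribosomal protein genes against the mean log2 CPM of the short RNAs Rmrp and Rpph1, 1 point per library, for the 10 WV libraries and for the 6 BAT libraries with short numbers. In WV, libraries FX_5497, FX_5503 and FX_5514 lie apart at 5.87 to 6.02.

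Lists of mitochondria, protein breakdown and other cell types were also lower in BATI4KO muscle. Nuclear-encoded subunits of oxidative phosphorylation had a median of -0.24 (76 of 78 negative; camera adjusted p = 8.01e-11), mitochondrial ribosomal proteins -0.13 (64 of 73 negative; camera adjusted p = 6.94e-07) and proteasome subunits -0.14 (25 of 31 negative; camera adjusted p = 0.00027). Each had an adjusted p = 0.629 with an estimated correlation, and 0 members passed adjusted over the list alone by edgeR's test. In the 7 libraries without FX_5497, FX_5503 and FX_5514, the ones with high Rmrp, the medians of these 3 lists were -0.11, -0.06 and -0.06 and none passed (camera adjusted p = 0.118, 0.0905 and 0.365). With the level of Rmrp and Rpph1 as a covariate they were -0.08, -0.07 and -0.02 and did not pass (camera adjusted p = 0.516, 0.219 and 0.702), and with the length correction -0.07, -0.01 and -0.03. Leaving out KO_5493 gave -0.16 for oxidative phosphorylation, KO_5492 gave -0.22 for mitochondrial ribosomal proteins and FX_5503 gave -0.08 for the proteasome. Fibroblast and preadipocyte markers had a median of -0.47 (camera adjusted p = 0.00014; adjusted p = 0.629 with an estimated correlation), with Dcn, a matrix proteoglycan, at 329 ± 170 against 165 ± 56.3 CPM and 4 lower adjusted over the list alone. Collagens and matrix genes had a median of -0.28 (camera adjusted p = 0.00404; adjusted p = 0.629 with an estimated correlation; 5 lower adjusted over the list alone), with Col12a1 at a log2 difference of -1.41. General adipocyte genes had a median of -0.26 (camera adjusted p = 0.0205; adjusted p = 0.629 with an estimated correlation; 1 lower adjusted over the list alone), with the transcription factor Cebpb at -0.82, and erythroid markers one of -0.31 (camera adjusted p = 0.0381; adjusted p = 0.629 with an estimated correlation; 0 lower). Macrophage markers had a median of -0.42 (camera adjusted p = 0.00582; 0 lower adjusted over the list alone; adjusted p = 0.699 with an estimated correlation). In the same 7 libraries collagens (-0.17, camera adjusted p = 0.514), macrophage markers (-0.72, 0.0506) and erythroid markers (-0.36, 0.0506) did not pass. With the level of Rmrp and Rpph1 as a covariate none of these 5 lists did: the camera adjusted p was 0.0676 for fibroblast (-0.46), 0.876 for collagen (-0.07), 0.0804 for general adipocyte (-0.27), 0.378 for erythroid (-0.07) and 0.219 for macrophage genes (-0.69). General adipocyte genes had a median of -0.15 with the length correction.

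Muscle atrophy genes had a median of -0.15 in WV (camera adjusted p = 0.0205; adjusted p = 0.629 with an estimated correlation), with 2 lower adjusted over the list alone. The direction of this list turned in the 7 libraries without FX_5497, FX_5503 and FX_5514 (median 0.001, camera adjusted p = 0.54) and with the level of Rmrp and Rpph1 as a covariate (+0.08, 0.219). Trim63, a ubiquitin ligase of muscle wasting, was at 277 ± 117 CPM in floxed and 168 ± 14.9 CPM in BATI4KO libraries, Foxo1, which switches on atrophy genes, had a log2 difference of -1.04, and Klf15 one of -0.71. Myogenic regulators had a median of +0.20 (12 of 15 positive; camera adjusted p = 0.00245; adjusted p = 0.629 with an estimated correlation; 0 higher adjusted over the list alone). Their median was +0.12 in the same 7 libraries (camera adjusted p = 0.514) and +0.08 with that covariate (0.793). No member of any WV list passed over all genes by edgeR's test. In the 7 libraries without FX_5497, FX_5503 and FX_5514, a subset chosen after seeing the data, 11 lists passed camera and 3 of them were among the 11 of all libraries: cytosolic ribosomal proteins, general adipocyte genes and fibroblast markers.

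Single libraries, scaling and filters also decided some of these WV calls. With library totals only 5 lists were higher and 11 lower, against 1 and 10, and the call for macrophage markers was lost (median -0.61, camera adjusted p = 0.0536), as it was with a filter of 1 CPM (-0.41, 0.06). Erythroid markers lost it without a filter (-0.29, camera adjusted p = 0.101) and with mitochondrial and globin genes left out (-0.25, 0.464), and their median was -0.56 with a filter of 1 CPM and -0.66 with quality weights. The call for macrophage markers was lost without library FX_5415 (median -0.15) or library KO_5493 (-0.31), for collagens without FX_5514 (-0.22) or KO_5493 (-0.16), and for erythroid markers without FX_5497 (-0.08) or KO_5494 (-0.31), while their median was -0.50 without KO_5492. General adipocyte genes lost it without FX_5415 (-0.12), KO_5494 (-0.28) or KO_5496 (-0.27), and had a median of -0.16 without KO_5493. Atrophy genes lost it without FX_5497 (-0.14), FX_5503 (-0.20) or FX_5514 (-0.20) or KO_5492 (-0.14) or KO_5494 (-0.15), and had a median of -0.23 without FX_5413. With library totals only, where the median of all WV genes was -0.12, atrophy genes had a median of -0.29. Under that scaling it was -0.25 for the proteasome, -0.22 for mitochondrial ribosomal proteins and +0.10 for myogenic regulators.

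The other 22 WV lists did not pass the camera test. Slow-twitch fibre genes had a median of +1.74 (adjusted p = 0.0599), with 2 of 5 BATI4KO libraries above the floxed mean. Adjusted p was 0.072 for granulocyte and mast cell markers (median -0.61), circadian clock genes (+0.10) and the stress response (-0.14), 0.0738 for immediate early genes (+0.15) and 0.0888 for regeneration and denervation genes (+0.18). It was 0.117 for the 3 mitochondrially encoded subunits (+0.33) and for smooth muscle and pericyte markers (-0.23), 0.277 for de novo lipogenesis (-0.10) and 0.285 for calcium handling of the sarcoplasmic reticulum (+0.05). It was 0.453 for fast-twitch and glycolytic genes (-0.06), translation factors and the mTOR pathway (+0.05) and the interferon response (-0.09). Nerve and Schwann cell markers (-0.18) and the myostatin and activin pathway (0.003, mean -0.03) had 0.459, lipolysis (-0.11) 0.53 and lymphocyte markers (+0.14) 0.604. Contractile and calcium-handling genes had a median of +0.01 and fatty acid oxidation genes one of 0.01 against a negative test direction (0.659 for both). The brown adipocyte programme (+0.02, against a negative test direction) had 0.758, endothelial markers (-0.04) 0.769 and the tricarboxylic acid cycle (-0.01, against a positive test direction) 0.954.

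The effect of genotype differed between the tissues for 3 of 16632 genes. Nthl1 had a log2 difference of +1.02 in BAT and -0.51 in WV, so that the BAT effect minus the WV effect was +1.51 (SE 0.22). Irf4 had a log2 difference of -2.45 in BAT and -0.48 in WV, and the effects differed by -1.98 (SE 0.31). Dusp10 had a log2 difference of -0.44 in BAT and +1.49 in WV, and the effects differed by -1.93 (SE 0.30). Each had an adjusted p of 0.0136 by the interaction term of edgeR's quasi-likelihood test, which takes the libraries as independent although 4 tags occur in both tissues. With limma voom and the tag as a random effect the call for Irf4 was lost (-1.86, limma adjusted p = 0.123). With library totals only Irf4 (-1.68, edgeR adjusted p = 0.101) and Dusp10 (-1.69, 0.0737) did not pass, nor did Dusp10 with the long tags alone in BAT (-1.90, 0.0604). Next in order and not passing were Clock, a core transcription factor of the circadian clock, at -0.36 in BAT and +0.48 in WV (edgeR adjusted p = 0.0834 for the difference), and Ptpn4 (-0.86), Cdc27 (-0.58), Peli3 (+1.17) and Adh1 (+1.25), each with an edgeR adjusted p of 0.192. Cdc27 overlaps Myl4 in the GRCm38.p6 annotation, so its counts are uncertain. Gstt2 (+1.15) and Rapsn (+1.48) had an edgeR adjusted p of 0.244. Unadjusted p-values under 0.05 were found for 1766 genes, against 832 expected by chance. The count was 30 without BATI4KO BAT library 2, 5 without BATI4KO BAT library 1 and 3 or 4 without any other library. It was 20 with the long tags alone in BAT, of which 2 were among the 3.

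Across 14104 genes tested in both tissues, the log2 differences of BAT and WV had a Pearson r of 0.168 and a Spearman rho of 0.118. This correlation is across genes, which are not independent replicates. With BAT differences from the libraries with short numbers, which share no tag with WV, r was 0.21, and with those from the long tags 0.059. Calls past the threshold in both tissues numbered 0 by edgeR's test, against 0.00035 expected for independent lists. At an unadjusted p under 0.005 in both tissues there were 9 genes, where independent tissues would give 4.87 in any direction, 0.749 higher in both and 1.52 lower in both. Elmod2, Gprc5c and Sec14l5 were higher in both, and Fmo1, Fmo2, Lonrf3, Ccbe1, Sulf1 and Dpep1 lower. As 4 tags occur in both tissues, independence may not hold.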

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

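The tests of a single muscle-rich library, of Mstn and carried-over muscle, of the short RNAs Rmrp and Rpph1, and of Elmod2 were chosen after the results were seen, as were the alternatives with these RNAs or with the muscle score on lists. Levels of named genes, list scores and total counts were checked within each group of 5 or 6 libraries. Of these 102 checks, 7 found a library standing apart from the rest, where chance gives about 1 in 20, or 5.1.

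Muscle genes were higher in BATI4KO brown fat, with a median log2 difference of +2.53 over 39 genes. Muscle tissue carried over at dissection would raise each gene by 1 common share of its level in muscle. From group means, 100% of the list, 39 of 39 genes, lay within 4-fold of the median share, 1.39%. Mstn needed 0.917 times that share. These means lean on BATI4KO library 3, whose share was 5.64%, against 0.261% to 1.15% in the other BATI4KO libraries. Mstn had 7 to 93 counts in BATI4KO libraries, so its mean also leans on its highest library. A band of 4-fold each way is wide, so this test is weak. Whether the genes of the list keep 1 common share without library 3 was not tested. The slow-fibre genes Myh7 and Myl2, outside this list, needed much larger shares. Mean Myh7 went from 2.75 to 26.1 CPM in BAT, against 45.5 CPM in floxed WV. Mean Myl2 went from 0.202 to 2.59 CPM, against 8.81 CPM. Myh7 ranged from 0.675 to 182 CPM between floxed WV libraries. Between BATI4KO BAT libraries Myh7 ran from 1.2 to 110 CPM (SD 41.5) and Myl2 from 0 to 13.4 CPM (SD 5.31). Each mean thus rests largely on its highest library, so these larger shares were not shown across libraries. Other slow-fibre genes outside the list were not compared in this way. With the muscle score as a covariate the log2 difference of Mstn was +0.45 (edgeR adjusted p = 0.929). This score takes up any gene that follows muscle RNA, carried over or made in brown fat, so it cannot tell these apart. From the shares, which lean on BATI4KO library 3, carried-over muscle is a candidate explanation for the contractile list and Mstn. BATI4KO library 3 was highest, but the difference was not in it alone. The list's median was +1.27 without it, and +2.01 within the long tags, which do not include it. BATI4KO libraries 1, KO_5414, KO_5492 and KO_5494 had shares of 0.629% to 1.15%, above every floxed library. BATI4KO library 2, at 0.261%, lay among the floxed ones. Whether the libraries other than 3 differ by genotype is not settled (exact permutation p = 0.06 over 100 relabellings). The shares per library were 0.0682% to 0.508% in floxed and 0.261% to 5.64% in BATI4KO libraries, and an effect of genotype on how the tissues adhere or on brown adipocytes themselves stays open and was not tested.

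Ribosomal protein genes were lower in BATI4KO muscle, with a median of -0.47. Gene length as the whole cause is argued against by 10000 random lists matched on length and expression, of which 0% had a median as low (range of the central 95%, -0.21 to -0.13), although those lists had a median of -0.17. Their members were drawn 1 by 1, while ribosomal protein genes move together (camera adjusted p = 0.629 with an estimated correlation). The 0% therefore overstates the strength of this evidence. Among the 7 libraries with low Rmrp and Rpph1 the gap between genotypes in the list score was 39.9% of that over all libraries, 0.19 against 0.48 (exact permutation p = 0.19 over 21 splits, the smallest possible being 0.0476). Over the 6 BAT libraries with short numbers the list score went with these RNAs at a Pearson r of 0.966 (permutation p = 0.0111, 0.0222 adjusted over r and rho) and a Spearman rho of 0.771 (permutation p = 0.103, 0.103 adjusted), and r was 0.812 without the 2 farthest libraries. The BAT libraries with long tags, where Rmrp was far lower, were left out of this correlation, so it holds for the short numbers only. Over the 6 BATI4KO BAT libraries of both title styles Rmrp ran from 11.7 to 701 CPM, while the list score had an SD of only 0.186. The score thus varied little over a wide range of Rmrp, which goes against a strong relation over all BAT libraries. Within these limits, a library difference in recovery of short RNAs is a candidate explanation for part of the lower median in muscle. The 3 libraries with high levels are all floxed, so genotype stays open.

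Elmod2 was higher in BATI4KO in both tissues, by +1.15 in WV and, without passing over all genes, by +1.02 in BAT (edgeR adjusted p = 0.14). Reads running through from its neighbour Ucp1 are argued against by Ucp1 itself, at most 0.299 CPM in any WV library, and chance by an unadjusted edgeR p of 0.000315 in BAT for a gene picked in WV. As 4 tags are shared between tissues, the BAT libraries with short numbers, which share no tag with WV, were also tested. They gave +1.12 (SE 0.30, edgeR unadjusted p = 0.00664, adjusted p = 0.656). Library KO_5414, whose tag is not in WV either, was not among them. The effects in both tissues did not differ beyond their error, by -0.569 standard errors (log2 -0.15, SE 0.26, edgeR adjusted p = 0.881). This does not show that they are equal, and the check was set after both effects were seen. A segment holding Elmod2 carried on a transgene built from the Ucp1 region is a hypothesis. A similar rise in both tissues does not single it out from other causes acting in both. The labels name no driver and do not say whether the floxed mice carry one. Other neighbours in the GRCm38.p6 annotation did not pass (Tbc1d9 +0.24 and +0.06, Scoc -0.33 and +0.14, Rnf150 +0.11 and +0.25 in BAT and WV), and an effect of Irf4 loss stays open.

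The effect of genotype differed between tissues, by the interaction term of edgeR's test, for Nthl1 (1.51), Irf4 (-1.98) and Dusp10 (-1.93). Gramd1a stood apart low in BATI4KO BAT library 3, at 50.4 CPM against 59.5 to 64.5 CPM. The lymphocyte score stood apart high in BAT library KO_5414, at 1.71 against 0.0211 to 0.546. The score of mitochondrially encoded subunits was 14 in floxed BAT library 3, against 13.6 to 13.7. In WV, Nr1d1 was at 68.2 CPM in library KO_5493 against 47.3 to 48.7 CPM, and Cecr2 at 41.9 CPM in the same library against 33.4 to 35.1 CPM. Cecr2 was at 30.1 CPM in library FX_5413 against 17.3 to 20.1 CPM. The general adipocyte score was 4.72 in WV library KO_5492, against 3.56 to 3.78.

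Other splits of the libraries were tested for each count. For the 7 BAT genes, 1 of 100 relabellings, the real one included, gave as many, the highest other being 1. This argues against chance for this count without excluding it. The 7 include Irf4, the targeted gene, several counts were tested, and 1 of 100 is the smallest share that 100 relabellings can give. Chance is not argued against for the others: 6 of 100 splits gave as many WV genes as the real 1 (highest other 1173), 5 of 100 as many as the 3 genes of the interaction (603), 29 of 100 as many as the 14 BAT lists (19), 69 of 100 as many as the 11 WV lists (22) and 10 of 100 a correlation between tissues as far from 0 as 0.168 (0.216). The WV split with 1173 genes set the 5 libraries with the highest scaling factors (1.04 to 1.302) against the rest (0.849 to 0.965), which points to a structure of these libraries other than genotype.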

How the results depend on the processing

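Alternatives that leave out the 3 WV libraries with high Rmrp, use these RNAs or gene length, use the muscle score on lists, permute list scores, test clock members or apply other scalings, filters, weights and left-out genes to lists were chosen after seeing the data. Irf4 in BAT kept its direction throughout and passed except with fewer samples: -2.43 with short numbers, -2.48 with long tags and -2.34 with short numbers and the replicate block. Without single libraries it ran from -2.62 to -2.21. The BAT count of 7 became 3 with upper-quartile scaling or a filter of 1 CPM, 388 with DESeq2, 12 with quality weights, 1 without the covariate or with the muscle score, 0 with short numbers and 0 with these and the block (1212 and 886 genes at an unadjusted p under 0.05); without single libraries, 1 to 16. Library totals gave 3 higher and 2 lower, against 3 and 4. Same-numbered BAT libraries had correlations of 0.134, -0.121 and 0.067, within the -0.234 to 0.17 of other pairs. With 3 libraries per genotype this cannot show whether the numbers pair the samples. With the replicate block 2 genes passed, of which 1, Irf4, was among the 7 (the other 6 at edgeR adjusted p = 0.0655 to 0.0944). With the block 13 lists passed, without general adipocyte genes (camera adjusted p = 0.0507). The WV count of 1 became 0 with upper-quartile scaling, library totals, 1 CPM, the length correction or 7 libraries (1294, 925, 1179, 1120 and 774 genes at an unadjusted p under 0.05), 5 without a filter, 97 with DESeq2, 9 with quality weights and 6 at an adjusted p under 0.10; without single libraries, 0 to 11. The interaction count of 3 became 20 with long tags alone in BAT and 3 to 30 without single libraries; library totals gave 3 higher and 0 lower. With limma voom and the tag as a random effect the interaction count was 3, of which 2 were shared with the main fit. Of 32 BAT lists 14 passed, and 0 with an estimated correlation, directional fry or permuted scores (0, 6 and 8 of the 32 at an unadjusted p under 0.05), 7 with mixed fry, 3 of them among the 14, 9 with long tags, 7 of them among the 14, and 9, all among the 14, with muscle, mitochondrial and globin genes left out; without single libraries, 11 to 18. Of 33 WV lists 11 passed, and 0 with an estimated correlation, directional fry or permuted scores (1, 2 and 1 of the 33), and 1 with mixed fry, the circadian clock, which was not among the 11; without single libraries, 9 to 14. The correlation between tissues became 0.059 with long tags. Direction turned, by values near 0, for 2 BAT lists with the muscle covariate, general adipocyte 0.004 and skeletal muscle -0.002, the latter by construction. It also turned for general adipocyte (0.071) and mitochondrial ribosomal genes (0.003) with library totals. With muscle genes left out it turned for the glycolytic genes that stayed in the fast-twitch list (-0.103). In WV it turned for atrophy genes, 0.001 in 7 libraries and 0.078 with the Rmrp covariate, and for Mstn, 0.176 and 0.257, and -0.222 to 0.127 without single libraries. Where not said, the cause was not tested. Depth limits Mstn and Lrrc7 in BAT, both under 2 CPM in mean.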

Other observations

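Circadian clock genes went different ways within each tissue, and their list did not pass camera in either. In BAT, 5 members were lower and 2 higher adjusted over the list alone by edgeR's test, and in WV 4 were higher and 2 lower. Cry1, a repressor of the clock, was at 21.5 ± 3.07 CPM in floxed and 12.6 ± 3.08 CPM in BATI4KO BAT, Per2 had a log2 difference of -0.46 and the output factor Dbp +0.53. In WV, Clock was at 55.7 ± 4.05 CPM in floxed and 77.8 ± 6.93 CPM in BATI4KO libraries, Nfil3 had a log2 difference of -0.61 and Bhlhe40 +0.78. The mixed fry test, which asks whether members change in either direction, gave an adjusted p of 0.00659 in BAT and 0.00411 in WV, and 0 members passed over all genes. This test compares the list with no change and not with other genes. In BAT 7 lists passed it, and in WV 1, the clock list. These examples, and the refits of this list, were chosen after their values were seen, and the labels give no time of day for the samples.

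Both clock counts changed when single libraries were left out. In BAT, 0 members passed over the list alone by edgeR's test without library FX_5497 (8 at an unadjusted p under 0.05), and 3 lower ones passed without FX_5503, 1 without KO_5492 and 2 without KO_5494. Without FX_5503 the mixed fry test did not pass (adjusted p = 0.0715). That library had 19.3 CPM of Arntl, against 2.42 to 4.47 CPM in the other floxed and 2.31 to 3.04 CPM in the BATI4KO libraries. Dbp was at 16.3 CPM in both FX_5497 and FX_5503, against 33.3 to 38.3 CPM in the other floxed libraries. Within the libraries with short numbers 2 members were lower (Dbp +0.07, Cry1 -0.51; mixed fry adjusted p = 0.198), and with long tags 4 were higher and 4 lower (Dbp +1.16, Cry1 -1.07; 0.000121). Without the covariate for title style 1 was lower (mixed fry adjusted p = 0.201), with the muscle score as a covariate 3 were (0.441), and with library totals only 2 were higher and 1 lower. With the replicate block 0 were higher and 1 lower (mixed fry adjusted p = 0.0281). With short numbers and the block 0 passed (0.492). In WV, 2 higher members passed without FX_5497, KO_5492 or KO_5493, 2 higher and 1 lower without FX_5514, and 3 higher without KO_5496, and without FX_5503 the mixed fry test did not pass (adjusted p = 0.0633). In the 7 libraries with low Rmrp and Rpph1 2 were higher, Nr1d1 (+0.93, against +1.18 in all libraries) and Clock (+0.52, against +0.48), and the mixed fry test did not pass (adjusted p = 0.528). Of the 4 others, Arntl (+0.69, against +0.65) and Per3 (-0.38, against -0.32) had differences no smaller than in all libraries, and Nfil3 (-0.39) and Bhlhe40 (+0.21) smaller ones. With the level of these RNAs as a covariate 0 passed (5 at an unadjusted p under 0.05 by edgeR; mixed fry adjusted p = 0.582), with Clock at +0.52, Nr1d1 at +0.83 and Bhlhe40 at +0.07, and with library totals only 1 was higher and 1 lower.

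Slow-twitch fibre genes varied widely between WV libraries of both genotypes. The list's mean log2 CPM was 8.10 in library KO_5495 and 8 in KO_5492, 6.65 in library FX_5514 and 1.85 in library FX_5503. Atp2a2, the calcium pump of slow fibres and heart, was at 66.7 ± 49.4 CPM in floxed and 224 ± 241 CPM in BATI4KO libraries (SD, n = 5 each) and did not pass (edgeR adjusted p = 0.53).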
